A study of Mus musculus with 6 samples.

How the data were processed

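Tumours were grown in female mice from 4T1 cells, a mouse mammary carcinoma line, and total RNA was taken from the tumour tissue. Per the labels' protocols, 300000 cells were implanted in the left mammary fat pad, and treatment began 2 weeks later. The groups are 3 tumours labelled saline and 3 labelled TTFM, for extracts of a Thai traditional formulary medicine. The composition, dose and length of the treatment are not given in the sources used here. The labels number the samples but do not say that each came from a separate mouse. P-values, except those of the list test camera described below, therefore measure only the spread between these samples, which may in part be technical.

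The authors deposited 1 table of 750 tumour-related genes by 6 samples. Its values were read as deposited whole-number counts per gene, not normalized. No label or header names the measuring platform, the counting steps or any normalization, which are not given in the sources used here. The reading as counts rests on the values themselves. They were whole numbers, the totals differed between samples, and every whole number from 1 up to at least 21 occurred in each column. A scan for a common multiplying factor from the gaps between low values gave best factors of 0.988 to 1.012 in 5 samples, with log-likelihood gains of 0.72 to 2.23 over no factor. For saline replicate 2 a factor of 0.9 gained 7.35, against 16.7 when the counts of saline replicate 3 were multiplied by 0.9 and rounded. A scaling of saline replicate 2 before deposit is therefore not excluded. The lowest value was 1 in every sample and no value was 0, so zeros may have been raised to 1 before deposit. No control-probe counts were used here, so background could not be subtracted.

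Gene names are those of the table. In a RefSeq gene table of the assembly GRCm38.p6, 740 of the 750 matched a current symbol and 10 matched 1 synonym, among them Whsc1 (Nsd2) and Skp1a (Skp1). The sources used here name no genome build, so no coordinates are given. The H3 histone genes Hist1h3b and Hist2h3b have near-identical copies, and how their signal was told apart is not given in the sources used here, so their levels are uncertain.

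Total counts per sample were 400274, 403124 and 422841 for saline replicates 1 to 3, and 426190, 449460 and 333515 for TTFM replicates 1 to 3. The 5 most abundant genes held 28.8% to 32.9% of the counts of a sample, and 199 to 226 genes had a count under 20. No pair of samples matched within sampling noise. Chi-square per degree of freedom over genes ran from 7.52 for TTFM replicates 1 and 2 to 150.3 for saline replicates 2 and 3. None was therefore treated as a library deposited a second time, which does not show that the samples came from separate animals.

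Genes with a mean count of at least 10 over the 6 samples were tested, which kept 627 and left out 123. Counts were scaled by trimmed mean of M values (TMM) factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest) in R 4.3.3, with TTFM against saline as the only term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error (SE) of a log2 fold change was the fold change divided by the square root of F. A normalized count is the count divided by the sample's total and TMM factor, times the mean of these products over the 6 samples. Fold changes are TTFM over saline on the log2 scale unless a fold is stated. The biological coefficient of variation fitted by edgeR was 33.4%, and the median SE of the log2 fold changes was 0.32.

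Of 34 gene lists fixed beforehand, 15 of cell type markers and 19 of pathways, those with at least 5 tested genes were compared with the other panel genes. This used camera (limma 3.58.1) with a preset correlation of 0.01, two-sided, on log2 CPM with a prior count of 1, adjusted over the lists. The background is therefore a panel already chosen for tumour genes. With a preset correlation, camera's p-values rest on the spread between genes, and they do not treat the samples as the only replicates. The score of a list in a sample is the mean over members of the log2 value centred on the gene's mean. Scores were compared by a two-sided exact permutation test, which with 3 samples against 3 cannot go below 0.1.

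The sample groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. Alternatives and tests said to be chosen or added after seeing the data or the results are exceptions. The rule names 12 genes in each direction. Genes past the threshold with no overlap between the groups come first, by size of change, and the places left are filled by smallest unadjusted p. It also names up to 4 members of smallest p for each list described, and 15 fixed genes, of which 3 are on the panel. Genes named outside the rule are said to be so where they appear. A few results the rule takes are not reported here.

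The alternatives were a replicate block, scaling to housekeeping genes, to the total or to the median, DESeq2 size factors, and DESeq2 1.42.0 or limma with trend in place of edgeR. Others were no filter, a mean count of at least 50, values under 20 raised to 20, and each sample left out in turn. For the lists they were a correlation estimated per list, and fry in place of camera. Pseudocount settings planned for normalized values do not apply to counts and were not run. The table labels no gene as housekeeping, and of the housekeeping list only Ercc3 and Ubb were tested, so that scaling rests on 2 genes. Intervals for the median of a gene set are 95% bootstrap intervals over genes from 10000 draws, and genes are not independent replicates.

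The procedure was tested on 20 simulated sets of the 627 genes, with 200 genes changed between 3 and 3 samples. It called 42.0% of genes changed 2-fold and 93.7% of genes changed 4-fold, and 2.90% of its calls were unchanged genes. With no gene changed, 4 of 20 sets gave any gene call and 1 of 20 gave any list call. With the inflammatory list lowered 2-fold, that list was called in 20 of 20 sets. Genes were drawn independently in these sets, so the list rates leave out correlation between genes. They may be too favourable for the measured samples. The shares of changed genes called may be too favourable as well. With 200 genes changed the adjusted threshold is easier to reach, and the sets held no structure between samples beyond the groups. An absence of gene calls in the measured samples therefore does not show that 4-fold changes were absent. Figures were drawn with matplotlib 3.10.9.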

Results

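Expression of 750 tumour-related genes was measured in 6 mammary tumours grown from 4T1 cells in female mice. Of these, 3 were labelled saline and 3 were labelled TTFM, the extracts of a Thai traditional formulary medicine. Totals ran from 333515 to 449460 counts per tumour, and 370 genes had a mean count of at least 100. The most abundant genes included Ubb, which encodes ubiquitin, with a mean count of 30600, Fn1 (fibronectin) with 25790, B2m (beta-2 microglobulin) with 22030 and Spp1 (osteopontin) with 21290. Uty, a Y-linked gene, had 4 to 12 counts in these female tumours, which gives a level for signal at the bottom of the range.

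The series has 1 comparison, which asks how gene expression in the tumours differed with TTFM treatment. Inflammatory cytokine and chemokine genes were lower as a group in TTFM tumours, with 13 of 15 tested members at negative log2 fold changes and a median 1.59-fold lower. With no filter on low values, 17 members were tested and the median log2 fold change was -0.37, against -0.67. That call of camera was lost with an estimated correlation (adjusted p = 0.202 with an estimated correlation) and without TTFM replicate 3 (0.0575). Granulocyte marker genes were also lower as a group, with 4 of 5 members negative and a median 3.08-fold lower. That call was lost with an estimated correlation (adjusted p = 0.202 with an estimated correlation), without saline replicate 2 (0.0942), without TTFM replicate 3 (0.0682) and without the shared gene Il1b (0.105). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, was the gene of smallest p in both lists. It had 2049.7 ± 705 normalized counts (SD, n = 3) in saline and 656 ± 177 (SD, n = 3) in TTFM tumours, a log2 fold change of -1.64 with an SE of 0.34. Its TTFM values of 803, 706 and 459.6 all lay below its saline values of 2289, 1257 and 2603.

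Gene by gene, 0 of 627 passed edgeR's quasi-likelihood test, and the smallest adjusted p was 0.525, for Il1b and other genes. At an unadjusted p under 0.05 edgeR gave 38 genes, 10 higher and 28 lower in TTFM tumours, where 31.4 are expected by chance. DESeq2 called 1 gene, Il1b (adjusted p = 0.0102), and limma with trend called 0. In 52 genes (8.29%) the 3 values of each group did not overlap, 25 higher and 27 lower in TTFM, where chance gives 10%.

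The gene values below are therefore differences that did not pass the test over all genes. Il1r2, the decoy receptor of interleukin-1, had 117 ± 47.4 normalized counts in saline and 37.8 ± 13.2 in TTFM tumours (SD, n = 3; log2 fold change -1.62, SE 0.40). Csf3r, the receptor of granulocyte colony-stimulating factor, stood at -1.66, Cd14, a monocyte and macrophage receptor for lipopolysaccharide, at -1.73, and the cytokine gene Osm (oncostatin M) at -1.81. Csf3r stood at -1.09 without saline replicate 3. In Csf3r, Cd14 and Osm saline replicate 2 lay within the range of the TTFM values. Its normalized count of Cd14 was 154, against 803 and 640.5 in the other saline tumours and 145 to 179.8 in TTFM tumours. Its count of Osm was 55.7, against 185 and 213 in saline and 27.8 to 60.9 in TTFM tumours. Its count of Csf3r was 107, against 254 and 438 in saline and 62.1 to 108 in TTFM tumours.

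Among other genes lower in TTFM tumours, the stress-induced Ddit4, an inhibitor of mTOR complex 1, had 1271 ± 420.3 normalized counts in saline and 602 ± 58.3 in TTFM tumours (SD, n = 3; log2 fold change -1.08). Thbs1, which encodes the matrix protein thrombospondin 1, had 2518 ± 418 and 1268 ± 378 (SD, n = 3; -0.99). Gadd45g stood at -1.07 and Dusp5, a phosphatase of ERK kinases, at -1.11. Nkd1, Arnt2 and Ccno stood at -1.43, -1.17 and -1.73, with TTFM means of 5.48, 6.53 and 5.37 normalized counts, at the level of Uty. With values under 20 raised to 20, Nkd1 stood at -0.0027, Arnt2 at 0.066 and Ccno at -0.13.

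Among genes higher in TTFM tumours, Pias1, which encodes a SUMO ligase, had 22.8 ± 4.88 normalized counts in saline and 56.1 ± 2.82 in TTFM tumours (SD, n = 3). Its log2 fold change was 1.29 with an SE of 0.30. Socs1, which encodes a suppressor of cytokine signalling, had 36.1 ± 8.07 and 72.8 ± 16.3 (SD, n = 3; 1.01). Tnfsf10, which encodes the death ligand TRAIL, stood at 0.77. The replication helicase gene Mcm7 stood at 0.59 and the histone methyltransferase gene Whsc1 at 0.74. Gnaq stood at 0.62, Etv1 at 0.55, Skp1a at 0.61, Nras at 0.44, Gng2 at 0.66 and Hhip at 0.84. Without TTFM replicate 1, Whsc1, Gng2 and Hhip stood at 0.49, 0.43 and 0.51. The groups did not overlap in any of these genes except Whsc1.

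**Figure D1:**
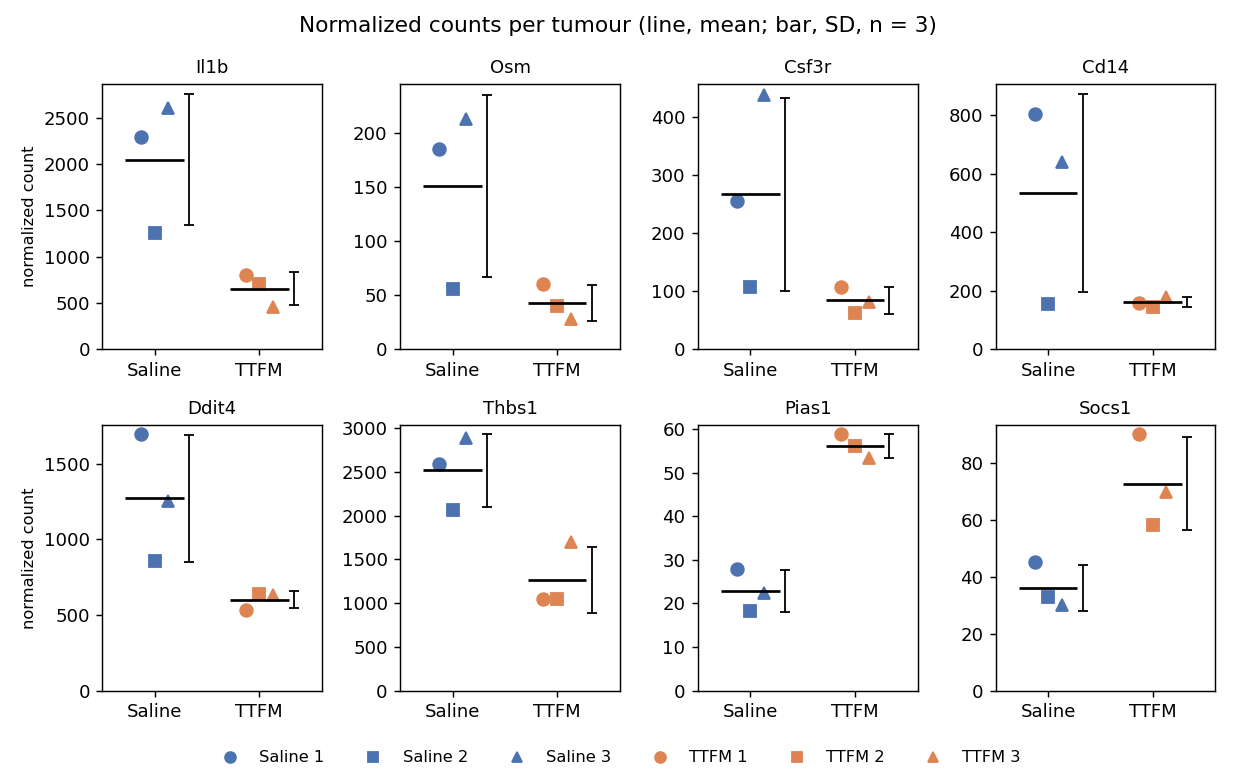
Normalized counts (vertical axis, from 0) of 8 genes in each tumour, saline in blue and TTFM in orange; horizontal lines are group means and bars are SD (n = 3). For Il1b the TTFM tumours lie between 459.6 and 803 and the saline tumours between 1257 and 2603, while for Cd14 saline replicate 2, at 154, lies among the TTFM tumours.

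The count of genes past the threshold rested on saline replicate 2. Without that tumour, edgeR's quasi-likelihood test called 14 genes, 13 lower and 1 higher in TTFM, with a smallest adjusted p of 0.00890 for Cd14. The lower genes were Il1b, Osm, Csf3r, Cd14, Ddit4, Dusp5, Fos, Socs3, Pim1, Irak2, Gadd45b, Bcl2l1 and Nfkbiz, the last named after its values were seen. Fos encodes a subunit of the AP-1 transcription factor and stood at -1.39 with all 6 tumours, Gadd45b at -1.50, Pim1 at -1.26 and Socs3 at -1.06. Nfkbiz stood at -0.90 and Bcl2l1, which encodes an inhibitor of apoptosis, at -0.74. Socs3 stood at -0.63 without saline replicate 1 and Bcl2l1 at -0.49 without saline replicate 3. The higher gene was Fst, which encodes follistatin and was also named after its values were seen, at 2.22 without that tumour and 0.10 with it. Of the 14 genes, 12 had an unadjusted p under 0.05 with all 6 tumours. The 2 fits share all the other tumours, so this overlap is no separate support. With any other tumour left out, edgeR's test called 0 genes.

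Of the 34 lists, 18 had at least 5 tested genes, and 2 passed camera. The inflammatory cytokine and chemokine list had a median of -0.67 and a camera adjusted p of 0.000766. The call was lost with an estimated correlation (adjusted p = 0.202 with an estimated correlation) and without TTFM replicate 3 (adjusted p = 0.0575). In it 5 members had an unadjusted p under 0.05, all lower: Il1b, Osm, Cxcl5 (-1.65), Tnf (-1.08) and, outside the naming rule, Cxcl2 (-2.09). Cxcl5 and Cxcl2 encode chemokines that attract neutrophils, and Tnf encodes tumour necrosis factor. Adjusted over the list alone, 1 member passed, Il1b (edgeR adjusted p = 0.0232), against 0 over all genes. Csf3 and Cxcl1, also outside the rule, stood at -0.82 and -0.83, and at -0.34 without saline replicate 1 and -0.31 without saline replicate 3. Fry, which tests whether the list's genes move on balance one way and does not compare them with other genes, gave an adjusted p of 0.0217. List scores were 0.48, 0.15 and 0.41 in saline and -0.21, -0.26 and -0.57 in TTFM tumours, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows.

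The list of neutrophil and granulocytic myeloid markers held 5 tested genes (median -1.62, camera adjusted p = 0.00375). The call was lost with an estimated correlation (adjusted p = 0.202 with an estimated correlation), without saline replicate 2 (adjusted p = 0.0942), without TTFM replicate 3 (0.0682) and without Il1b (0.105), the last chosen after seeing the data. Adjusted over the list alone, 3 passed, Il1b, Il1r2 and Csf3r, all lower in TTFM, against 0 over all genes in edgeR's test. Mpo, the neutrophil enzyme myeloperoxidase, stood at -0.86 and Mmp9, a matrix metalloproteinase named outside the rule, at 0.59 with an SE of 0.91. With 1 tumour left out, Mpo ran from -1.46 to -0.085 and Mmp9 from 0.12 to 2.14, with -0.085 and 2.14 both without saline replicate 2. Il1b is a member of both lists. List scores were 0.29, 0.65 and 0.44 in saline and -0.35, -0.26 and -0.77 in TTFM tumours, with an exact permutation p of 0.1. The score of saline replicate 2 drew in part on Mmp9, with 5510 normalized counts there against 1164 and 468 in saline replicates 1 and 3. Its Csf3r lay within the range of the TTFM values.

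**Figure D2:**
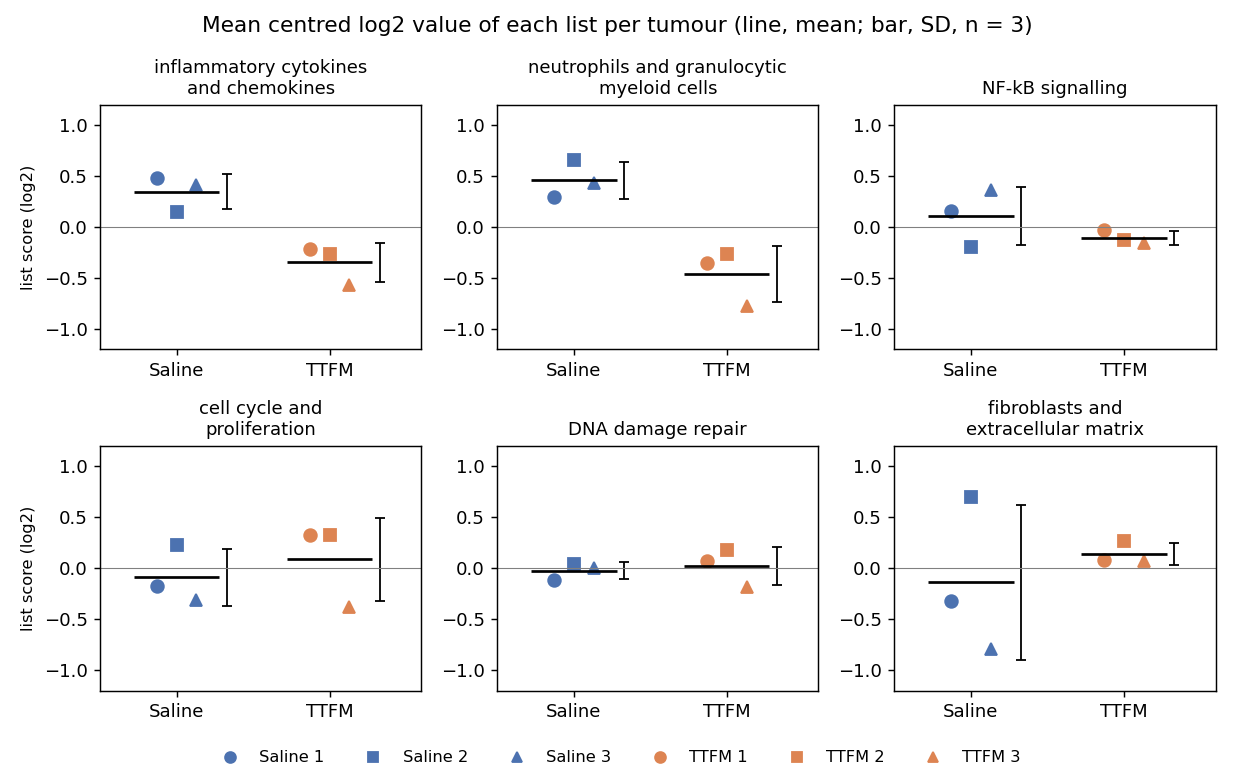
List scores (vertical axis, mean of centred log2 values) of 6 gene lists in each tumour, saline in blue and TTFM in orange; horizontal lines are group means and bars are SD (n = 3). The inflammatory list lies at 0.15 to 0.48 in saline and -0.57 to -0.21 in TTFM tumours, while matrix scores in saline run from -0.79 to 0.70.

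The cell cycle and proliferation list did not pass camera (27 genes, median 0.22, adjusted p = 0.389). In it 19 members were positive, among them Mcm7, Top2a (topoisomerase II alpha, 1.09), the replication clamp gene Pcna (0.52) and Mcm4 (0.42). With 1 tumour left out, Top2a ran from 0.74 to 1.79, Pcna from 0.34 to 0.81, Mcm4 from 0.19 to 0.87 and the list's median from 0.044 to 0.54, each highest without saline replicate 2. Its scores were -0.18, 0.22 and -0.31 in saline and 0.32, 0.32 and -0.38 in TTFM tumours, and it passed only without TTFM replicate 3 among the settings with 1 tumour left out (adjusted p = 0.00526). NF-kB signalling did not pass (14 genes, median -0.15, camera adjusted p = 0.565), with Irak2 at -1.30, the receptor gene Tlr2 at -0.83, the inhibitor gene Nfkbia at -0.45 and Rela at -0.43. Without saline replicate 3, Nfkbia stood at -0.17 and Rela at -0.14. The median of the NF-kB list ran from -0.33 (without saline replicate 2) to -0.068 (without TTFM replicate 3). DNA damage repair did not pass (37 genes, median 0.12, camera adjusted p = 0.771), with 23 members positive and Gadd45g and Gadd45b among those on the lower side. Its median, with 1 tumour left out, ran from 0.0073 (without TTFM replicate 2) to 0.26 (without TTFM replicate 3). Hypoxia and glycolysis did not pass (5 genes, median -0.07, adjusted p = 0.968), its median running from -0.20 (without TTFM replicate 1) to 0.076 (without saline replicate 2), and adjusted over the list alone 1 member passed, Ddit4 (edgeR adjusted p = 0.0248).

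Fibroblast and extracellular matrix genes varied widely between tumours of a group, and the list did not pass (19 genes, camera adjusted p = 0.852). Its median was 0.13 and its mean -0.04, with the camera direction up. The median ran from -0.17 (without saline replicate 3) to 0.80 (without saline replicate 2). Thbs1 lay lowest in p, followed by Col11a2 (-1.04, SE 0.76), the laminin gene Lama5 (-0.30) and the growth factor receptor gene Pdgfra (0.38). The value of Col11a2 ran from -1.90 (without TTFM replicate 3) to -0.40 (without saline replicate 3), Lama5 from -0.49 (without saline replicate 2) to -0.17 (without saline replicate 3) and Pdgfra from -0.024 (without TTFM replicate 3) to 0.63 (without TTFM replicate 1). Scores were -0.32, 0.70 and -0.79 in saline and 0.08, 0.27 and 0.07 in TTFM tumours. Without saline replicate 2 the list passed, higher in TTFM (adjusted p = 0.0453). Col1a1, a collagen gene named outside the rule, had 4437, 18640 and 1516 normalized counts in the saline tumours and 8646, 11540 and 6644 in the TTFM tumours.

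None of the other 11 tested lists passed camera. Endothelial cells and vessels had a median of -0.19 (adjusted p = 0.852), cell adhesion and integrins 0.08 (0.852) and epithelial and tumour cell markers -0.07 (0.977). TGF-beta signalling and mesenchymal transition had a median of -0.05, Notch and Hedgehog signalling -0.06, WNT signalling 0.12, JAK-STAT signalling and cytokine receptors -0.16, and p53 and apoptosis -0.02. RAS and MAPK signalling had a median of 0.0031, chromatin modification 0.0020 and PI3K, AKT and mTOR signalling -0.04, and each of these 8 had an adjusted p of 0.968. The medians of all 11 turned in sign or moved by over 1.5 times with 1 tumour left out. Median, mean and test differed in sign for the p53, Notch and Hedgehog, RAS and MAPK, and chromatin lists.

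A further 16 lists had fewer than 5 tested genes. Oxidative stress and xenobiotic response had 4 tested genes, all on the lower side without passing edgeR's test: the heat shock genes Hspa1a (-1.42, SE 0.78), uncertain because of its near-identical copy Hspa1b, and Hspb1 (-1.10, SE 0.50), Ddit3 (-0.75, SE 0.34) and Nfe2l2 (-0.57, SE 0.33). Cytotoxic lymphocytes had Gzmb (0.39, SE 0.71), Ifng (-0.49, SE 0.51) and Fasl (-0.25, SE 0.46). NK cells had 2 tested genes, including Il2rb (1.08, SE 0.53), macrophages had Cd14 and Csf1r (0.41, SE 0.31), and the interferon response had 2, including Socs1. Mitochondrial and lipid metabolism had 3. Regulatory T cells and checkpoints, dendritic cells, mast cells, adipocytes, and antigen processing and presentation had 1 each. T cells, B and plasma cells, skeletal muscle, erythrocytes and complement had 0, so the levels of these cells could not be judged. Of the 15 fixed genes the panel held Vegfa (0.16, SE 0.47), the epithelial cadherin gene Cdh1 (0.17, SE 0.28) and the tumour suppressor gene Trp53 (-0.33, SE 0.28).

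The tumours did not separate by treatment over all genes. The first principal component held 56.8% of the variance and placed saline replicates 1, 2 and 3 at -9.57, 9.92 and -13.7 and TTFM replicates 1, 2 and 3 at 7.46, 8.91 and -3.08. Across genes, whose values are not independent replicates, the correlation of saline replicate 2 was 0.973 and 0.981 with TTFM replicates 1 and 2, against 0.929 and 0.906 with saline replicates 1 and 3. The genes of highest weight on the side of saline replicate 2 were the collagen genes Col11a1 and Col3a1 and Mmp9. On the other side they were Ifna1, Kitl and the collagen gene Col4a5, all named after the weights were seen. Of these, Ifna1 is uncertain because of near-identical copies and a mean count of 12.7, near the level of Uty. Also of high weight on that side were Cd14, Cxcl5, Cxcl2, Csf3r, Osm, Irak2, Gadd45b, Fos and Pim1. Il11 and Mmp9, members of the inflammatory and granulocyte lists, lay on the side of saline replicate 2. The differences in these genes thus lay partly along a component that did not separate the tumours by treatment.

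**Figure D3:**
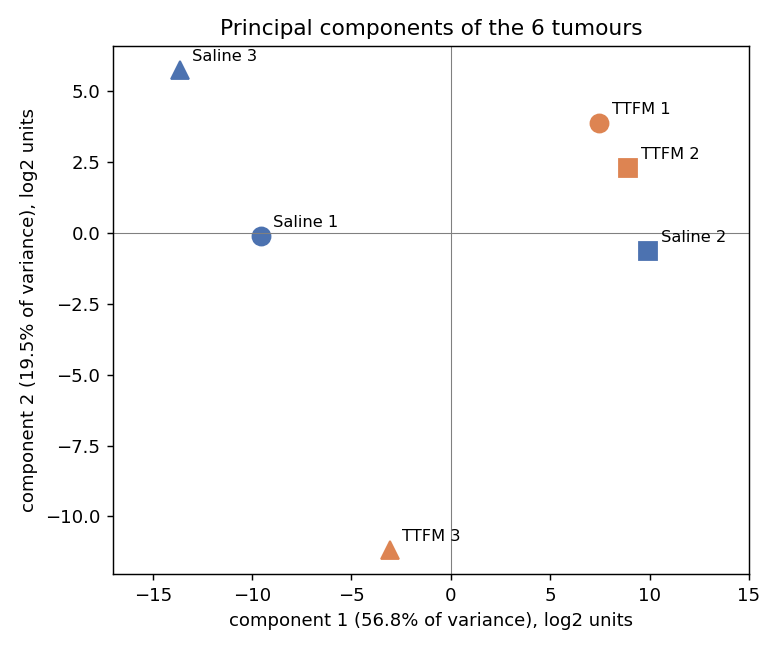
Principal components 1 (horizontal) and 2 (vertical) of log2 values over 627 genes, in log2 units, with 1 point per tumour, saline in blue and TTFM in orange. Saline replicate 2, at 9.92 on the first component, lies beside TTFM replicates 1 and 2 at 7.46 and 8.91.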

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

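The count of genes past the threshold was 0 with edgeR under every scaling, filter, the raised floor and the replicate block. It was 0 with limma with trend and 1 with DESeq2, and 0 to 14 with 1 tumour left out, the 14 without saline replicate 2. Genes at an unadjusted p under 0.05 in edgeR numbered 10 higher and 28 lower. With 1 tumour left out they numbered 1 to 58 higher and 10 to 62 lower, and with the block 16 and 25. Scaling to the total gave 6 higher and 28 lower, and to the housekeeping genes 5 and 23. The number of lists past the threshold was 2 under every scaling, with no filter and with the block. For the lists, DESeq2 size factors were an alternative added after seeing the data (adjusted p of 0.000691 for the inflammatory and 0.00329 for the granulocyte list). Under scalings, filters and the block, the median log2 fold change ran from -0.82 (mean of at least 50) to -0.37 (no filter) for the inflammatory list and from -1.72 to -1.49 for the granulocyte list. It ran from 0.052 to 0.31 for the matrix list, -0.23 to -0.083 for NF-kB and 0.060 to 0.18 for DNA repair. Fry, which does not compare a list with other genes, also gave 2. It was 1 with a mean count of at least 50, where the granulocyte list had too few genes, and 1 to 2 with 1 tumour left out. It was 0 with an estimated correlation (adjusted p = 0.202 for both lists), and 1 without Il1b in the granulocyte list (0.105), an alternative chosen after seeing the data. The estimated correlations were -0.042 for the inflammatory and -0.108 for the granulocyte list, both below the preset 0.01. A higher correlation between members therefore does not account for the calls lost with an estimated correlation. With 1 tumour left out the adjusted p ran from 4.2e-06 to 0.0575 for the inflammatory list and from 0.00017 to 0.0942 for the granulocyte list. The cause of the moves in the other settings was not tested, beyond the smaller number of samples or genes.

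Whether the replicate numbers pair the samples stays undecided. Deviations of same-numbered tumours from their group means correlated at -0.228, 0.435 and 0.265 across genes, with no other pairings set beside them. Among TTFM tumours, saline replicate 1 correlated best with replicate 3 (0.962). Saline replicate 2 correlated best with the same-numbered TTFM tumour (0.981), as did saline replicate 3 (0.938). With the replicate block, 0 genes and 2 lists passed, as without it, with adjusted p of 0.000972 for the inflammatory list and 0.0229 for the granulocyte list.

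Of the named genes' values under the alternatives, 899 kept their direction and side of the threshold, 15 passed it in the same direction and 12 turned in sign, none of them called, and the cause was not tested. With 1 tumour left out, 30 of 59 named genes turned in sign or moved by over 1.5 times. Log2 fold changes then ran from -0.17 to 0.84 for Vegfa, -0.024 to 0.63 for Pdgfra, -1.84 to 0.12 for Hspa1a, -0.83 to 0.82 for Gzmb, -0.56 to 0.15 for Fasl, -1.41 to -0.53 for Hspb1, -0.81 to -0.38 for Nfe2l2, 0.49 to 1.498 for Il2rb, -0.95 to -0.086 for Ifng, 0.15 to 0.71 for Csf1r, 0.037 to 0.38 for Cdh1, -0.57 to -0.12 for Trp53 and -0.36 to 2.22 for Fst. With values under 20 raised to 20, Arnt2 and Fasl, all of whose values were then 20, stood at 0.066 and Fst at -0.028, and with housekeeping scaling Fst stood at -0.041. Among lists not past the threshold the direction turned with an adjusted p of 0.936 for the epithelial and the PI3K lists under housekeeping scaling, and 0.981 for both under median scaling. With no filter it turned at 0.833 for the PI3K list, 0.848 for the RAS and TGF-beta lists and 0.934 for the WNT list. It turned at 0.98 for the Notch list with a mean of at least 50 and 0.985 for the chromatin list with fry. Lists that turned in at least 1 of the settings with 1 tumour left out had, over all 6 of these, adjusted p of 0.0453 to 0.976 (matrix, which turned without saline replicate 3 at 0.713 and passed in its main direction without saline replicate 2 at 0.0453), 0.709 to 0.976 (epithelial, RAS and chromatin), 0.713 to 0.976 (hypoxia and PI3K), 0.713 to 0.911 (Notch) and 0.601 to 0.976 (JAK-STAT). Depth limits genes with counts near the level of Uty, such as Fasl and, in TTFM tumours, Nkd1, Arnt2 and Ccno.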

Other observations

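The tests in this part were chosen after the main results were seen. For other leukocyte genes, list counts over other splits and the correlation without matrix genes, the rule was written before its own outcome was seen. Of 22 FGF ligand genes on the panel, 8 never exceeded 12 counts, the highest count of Uty in any tumour, and 0 had a mean count of at least 100. Fgf7 was the highest, with a mean count of 50.8. Of 15 WNT ligand genes, 4 never exceeded 12 counts, and Wnt5a was the highest with a mean count of 445. Of 16 interleukin genes, 4 never exceeded 12 counts, and Il1b was the highest with a mean count of 1408. Cdkn2a, which encodes cell cycle inhibitors, had 1.00 to 6.74 normalized counts over the 6 tumours, while the related Cdkn2b had 17.2 to 44.4 and Cdkn2c had 359.8 to 731. Over the whole panel, 74 of 750 genes never exceeded 12 counts.

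A few matrix and protease genes, chosen after their values were seen, varied widely between saline tumours. Col3a1 had 1038, 8162 and 312.5 normalized counts in saline replicates 1 to 3 and 3784, 5802 and 2449 in TTFM replicates 1 to 3. Tnc, which encodes tenascin C, had 5634, 24090 and 1675 against 11860, 14000 and 9714. Mmp9 had 1164, 5510 and 468 against 5082, 4689 and 996. The proliferation gene Top2a had 274, 615 and 154 against 1047, 922 and 241. Fn1 ranged only 1.65-fold and Spp1 2.01-fold over the 6 tumours.

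The inflammatory and granulocyte lists together had 19 tested members, 16 of them lower in TTFM tumours, with a median log2 fold change of -0.82. The choice among the 5 scalings does not account for this, since the median stayed at -0.73 or below under all of them. These scalings differed little from each other. The median over all tested genes ran only from -0.041 (total) to 0.051 (housekeeping genes). A background in saline tumours of 12 counts, the highest Uty count, is too small to account for the 9 members with a mean count of at least 100. After 12 counts were taken from every saline value, these 9 kept a median of -0.78 (95% bootstrap interval -1.63 to -0.13), against -0.81 before. So small a subtraction could hardly have moved members of that count. The test therefore does not decide on a background above 12 counts. That test replaced an earlier one, which set a stricter bound on the same 9 members with nothing subtracted and was undecided (median -0.82, interval -1.67 to -0.21). The 10 members of lower count (median -0.76), where background weighs more, were not covered. A fall of all leukocytes as large as that of these lists is argued against by 30 other leukocyte genes, 15 of them lower. Their median was 0.035 (interval -0.22 to 0.26, range -1.05 to 1.08). With the macrophage gene Cd14 (-1.73), left out of that set and added after its value was seen, it was -0.0027 (interval -0.24 to 0.23). Some of the 30 lie near the floor, such as Fasl, or are not particular to leukocytes, such as Myd88 of the NF-kB list. The T-cell and B-cell lists had 0 tested genes. A smaller fall, or one in a single cell type such as myeloid cells, is therefore not excluded. A weaker induction of immediate-early genes, through treatment or through handling of the tissue, may contribute and stays open, with a median of -0.40 over 13 such genes (interval -0.74 to 0.05), as does an effect of TTFM on myeloid cells, which was not tested.

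Splits of the 6 tumours into 3 and 3 number 10, too few for a share under 0.05. The real split gave 0 genes past edgeR's threshold (DESeq2 1, limma 0), a count that all 10 splits must reach, so it tests nothing. At an unadjusted p under 0.05 it gave 38 genes, and 3 of the 10 splits gave as many. The highest other split gave 104 genes past the threshold and 220 at an unadjusted p under 0.05, with saline replicates 1 and 3 and TTFM replicate 3 on the same side, which points to a structure of the samples that the labelled treatment does not follow. For lists the real split gave 2, the highest other 3, and 4 of the 10 splits gave as many. The smallest unadjusted camera p of any list was 8.1e-06 in the split with 104 genes, against 4.26e-05 in the real split.

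Saline replicate 2 lay closer to TTFM replicates 1 and 2 than to the other saline tumours over all genes, by 0.060 in mean correlation. Background in genes of low count is argued against by 370 genes with a mean count of at least 100, over which the excess was 0.115. The genes of the matrix list alone are argued against by the 608 genes outside that list, over which it was 0.0515. Those 608 still held matrix and protease genes of high weight on the first component, such as Col5a2 and Mmp9. A part of matrix genes as a whole is therefore not excluded. An exchange of saline replicate 2 with TTFM replicate 3 stays open. TTFM replicate 3 correlated about equally with both sides, 0.00215 higher with saline replicates 1 and 3 than with TTFM replicates 1 and 2. The groups after such an exchange are those of the split with 104 genes past edgeR's threshold, against 0 under the labels. In that split only the cell cycle list passed camera, and neither the inflammatory nor the granulocyte list did. The higher gene count alone does not show that an exchange took place. Scores over the inflammatory and granulocyte lists ran as labelled (0.40, 0.28 and 0.38 in saline, -0.23, -0.24 and -0.58 in TTFM). These lists were called under the labels and so cannot decide on the exchange. A wrong label on saline replicate 2 alone, and differences between tumours in stroma or growth, may also account for the pattern and stay open, untested.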
